A study of Mus musculus with 24 samples.

How the data were processed

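Gene expression was measured by bulk RNA sequencing in 24 mouse samples. The labels call the tissue pancreatic tumour, while the sample titles say muscle. Skeletal muscle genes took at most 0.0493% of the counts of any library, which argues against muscle, and the samples were treated as pancreatic tumour. The samples fall into 4 groups of 6, a control group given PBS (buffered saline) and groups named GEM, IGEL and LIGEL, all collected on day 24. The abbreviations are not expanded in the labels, so no drug or carrier is assigned to a group here. The labels name no pairing, cage or batch. They do not state that the 6 samples of a group came from 6 animals, so p-values measure only the spread between these samples, which can be technical in part.

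The submitters described tumours frozen on dry ice, RNA extracted with Trizol and checked on an Agilent instrument, and Illumina libraries. Their processing notes name HISAT2, featureCounts of Subread and the mouse build mm10, without versions. Strandedness and the annotation release were not given in the sources used here. The authors supplied 1 table of raw read counts per gene, with no normalization, for 54532 genes with their coordinates. Of these, 54409 identifiers are in GENCODE mouse release 21, and 53462 of them have identical chromosome, start and end there, so coordinates are on mm10. Each sample is 1 column of that table, matched to its label by name.

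Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 4 groups (min.count 10, min.total.count 15), which left 19253 genes and removed 0.0666% of all counts. Libraries were scaled with TMM factors. All 24 samples entered 1 quasi-likelihood model with a mean per group, robust estimation, and the quasi-likelihood F test for each of 6 contrasts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. CPM values scale each library by its TMM-scaled total, log2 CPM adds a prior count of 2, and values are given as mean ± SD.

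Gene lists were 39 sets of marker and pathway genes, 641 genes in all, of which 640 are in the table. They cover immune cells, antigen presentation, interferon, stroma, drug response, tumour epithelium and tissues that a piece of tumour can also hold. Each list was tested per contrast with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and called at an adjusted p under 0.05 over the 39 lists. Camera asks whether a list's genes moved more than the other genes. The same test with the correlation estimated from the residuals is given beside each call. Fry asks whether a list's genes move one way on balance and compares them with no other genes. An exact two-sided permutation test of each list's mean log2 CPM per library was added, where the smallest possible p is 0.00216 for 6 against 6 samples and the same for 6 against 5. Where a count of list members is given as adjusted over the list alone, the gene p-values were adjusted within that list only.

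Genes named in the text follow a rule with 3 parts. The first takes up to 10 higher and 10 lower genes per contrast with the largest change among called genes with an absolute log2 fold change of at least 1, a mean of at least 1 CPM in the higher group, and at least 5 of the 6 samples of the first group beyond the median of the second. It leaves out predicted genes, pseudogenes and the V, D and J segments of antibody and T cell receptor genes. The second takes the 4 members with the smallest p of each called list. The third takes 12 fixed genes in every contrast, among them Cd8a, Cd274, Col1a1, Agtr1a, Mki67 and Cpa1. Xist, Ptprc, Krt8, Krt18 and the Y-linked genes lie outside the rule and were named after their values were seen. The groups, contrasts, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

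Other settings chosen beforehand were DESeq2 1.42.0, limma voom with sample quality weights, RLE scaling, library totals without a composition factor and no expression filter. Further ones used only the 12 samples compared, or left out the 3 libraries whose count columns end in _2. Also chosen beforehand were the replicate number as a block, the acinar or the skeletal muscle score as a covariate and a fold change minimum. The last left out each sample in turn. Chosen after seeing the data were a focus on PBS replicate 5, the first part of the naming rule on the fit without that library, the settings for the 6 libraries whose count columns are named A1, A2 or A3 with a suffix (A7 to A24 in the rest), removal of PBS replicates 1 and 5 together, combinations of these, and the exact permutation of list means. Without a composition factor the median log2 fold change of all genes in LIGEL against PBS was 0.10, against -0.03 with TMM factors.

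Library totals ranged from 27.1 to 40.5 M. Shares of a single library are given with Wilson 95% confidence intervals, which cover counting error only, as read counts without molecular identifiers are not independent molecules. Among 60 pairs of samples within groups, the chi-square per degree of freedom over genes with at least 50 counts in the pair ranged from 17.4 to 2000, so no pair differed by counting noise alone. Whether 2 libraries came from the same tumour cannot be read from this. The smallest value belongs to LIGEL replicates 1 and 2, whose columns share the name A3. GEM replicates 2 and 3 share the name A2, at 60.2. The name A1 is shared across groups, by IGEL replicate 1 and GEM replicate 1. What a shared name means is not given in the sources used here. The models were tested on counts simulated for all 24 samples, with 200 genes changed in LIGEL and the 18 T cell genes raised there too. Genes were drawn independently and no library stood apart, unlike in the real data, so the false calls need not carry over. At a 2-fold change edgeR called 114 of them with 7 false calls among 121, DESeq2 131 with 27 among 162, and voom 108 with 7 among 115. At a 4-fold change the numbers were 182 with 11 among 205 for edgeR, 188 with 31 among 235 for DESeq2, and 176 with 5 among 192 for voom. The remaining calls at either fold were raised T cell genes outside the 200, which count as neither recovered nor false.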

Results

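Gene expression was measured in 24 mouse pancreatic tumour samples, 6 each from the PBS control, GEM, IGEL and LIGEL groups, all from day 24. The series title speaks of stromal remodelling with losartan, an angiotensin receptor blocker, followed by a nanocarrier for chemo-immunotherapy. The comparisons therefore ask how stroma, immune cells and tumour cell programmes differed between each treated group and control, and between the treated groups. Total counts per library (M, counts in units of 1e6) averaged 33.6 ± 3.25 M in PBS, 33.7 ± 1.42 M in GEM, 35.4 ± 2.25 M in IGEL and 35.6 ± 3.604 M in LIGEL (mean ± SD, n = 6 each).

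The libraries differed most in transcripts of pancreatic acinar cells, which make digestive enzymes. The 26 acinar genes took a median of 2.53% of counts in PBS, 1.67% in GEM, 1.28% in IGEL and 0.904% in LIGEL. PBS replicate 5 stood far apart with 45.7% (Wilson 95% interval 45.7 to 45.7%), and its total of 27.1 M and its TMM factor of 0.548 were the lowest of the 24. GEM replicate 6 followed with 19.1% (19.1 to 19.1%), IGEL replicate 4 with 11.01% (10.999 to 11.02%), LIGEL replicate 4 with 8.73% (8.72 to 8.74%) and PBS replicate 1 with 6.95% (6.94 to 6.95%). The first principal component held 48.3% of the variance and the second 10.1%. IGEL replicate 4 alone carried clear skeletal muscle transcripts, with Acta1 at 33.1 CPM and Ttn at 139 CPM against at most 0.327 and 10.6 CPM elsewhere. The muscle genes still took only 0.0493% of its counts (0.0485 to 0.05001%).

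**Figure D1:**
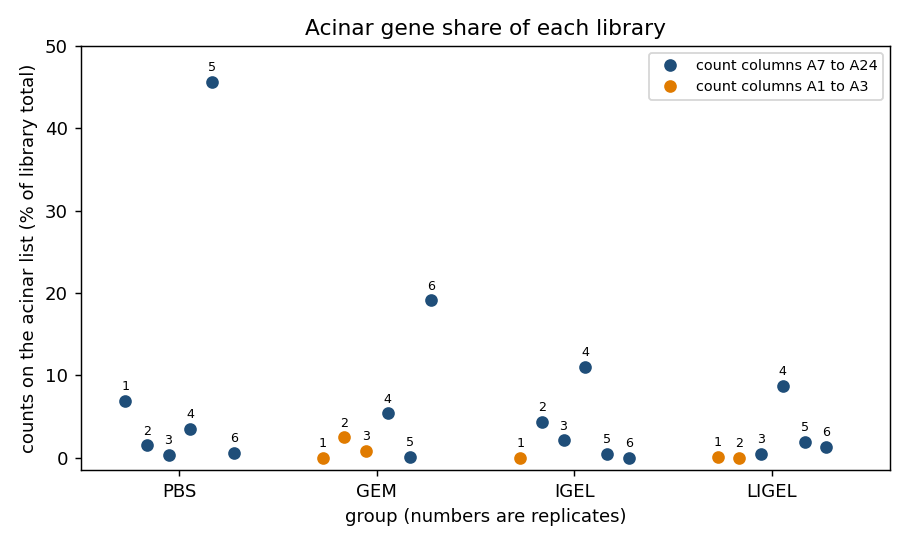
Share of counts on 26 acinar genes, in percent, for each library by group, orange for the A1 to A3 libraries. PBS replicate 5 lies at 45.7%, above GEM replicate 6 at 19.1% and all others.

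A second difference followed the names of the count columns. In 6 libraries the columns are named A1, A2 or A3 with a suffix, against A7 to A24 in the rest. The 6 are GEM replicates 1, 2 and 3, IGEL replicate 1, LIGEL replicates 1 and 2, and none of PBS. With PBS replicate 5 removed, 468 genes differed between these 6 and the rest within groups, 204 higher and 264 lower. Type I interferon genes, which cells switch on against viruses, had a median log2 difference of -1.22 and 19 of 24 passed as lower (camera adjusted p = 2.18e-31, and adjusted p = 0.149 with an estimated correlation). Interferon gamma genes lay at -1.11 with 12 of 21 lower (camera adjusted p = 9.64e-23), and hypoxia genes at 0.96 with 8 of 18 higher (camera adjusted p = 5.25e-22). Both had an adjusted p = 0.149 with an estimated correlation. Proliferation genes lay at -0.51 with 12 of 27 lower (camera adjusted p = 5.33e-18, adjusted p = 0.246 with an estimated correlation). Class I presentation lay at -0.41 with 7 of 14 lower (camera adjusted p = 1.27e-10, adjusted p = 0.195 with an estimated correlation), and acinar genes at -5.06 with 0 of 26 passing (camera adjusted p = 4.61e-14, adjusted p = 0.436 with an estimated correlation). Camera also called collagens and matrix (-0.48, camera adjusted p = 0.000348), islet (-2.34, 0.000147), endothelium (-0.39, 0.00330) and class II genes (-0.59, 0.0283) lower. Nucleoside analogue handling (-0.18, 0.0134) and liver genes (-1.22, 0.0300) were called lower too, and the unfolded protein response higher (0.16, 0.00152). For these lists the adjusted p with an estimated correlation was 0.267 to 0.680. PBS holds no such library, so a comparison with PBS can be recomputed only without these libraries or with a term for them, and values are given where either changed a call.

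No single gene passed the edgeR test in any of the 6 comparisons with all 24 samples. At an unadjusted p under 0.05 there were 926 genes in GEM against PBS, 2896 in IGEL against PBS and 3945 in LIGEL against PBS, where chance gives 963. There were 242 in LIGEL against IGEL, 305 in IGEL against GEM and 608 in LIGEL against GEM. DESeq2 called 0, 42 and 1224 genes in the comparisons of GEM, IGEL and LIGEL with PBS, and voom with quality weights called 66, 384 and 728. Both called 0 between treated groups. The quality weights were 0.0778 for PBS replicate 5 and 0.249 for PBS replicate 1. In a fit without PBS replicate 5, a library singled out after its values were seen, edgeR called 0 genes in GEM, 18 in IGEL and 173 in LIGEL against PBS. The same fit called 0 between treated groups, with 379, 475 and 1021 genes at an unadjusted p under 0.05 in LIGEL against IGEL, IGEL against GEM and LIGEL against GEM.

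**Figure D2:**
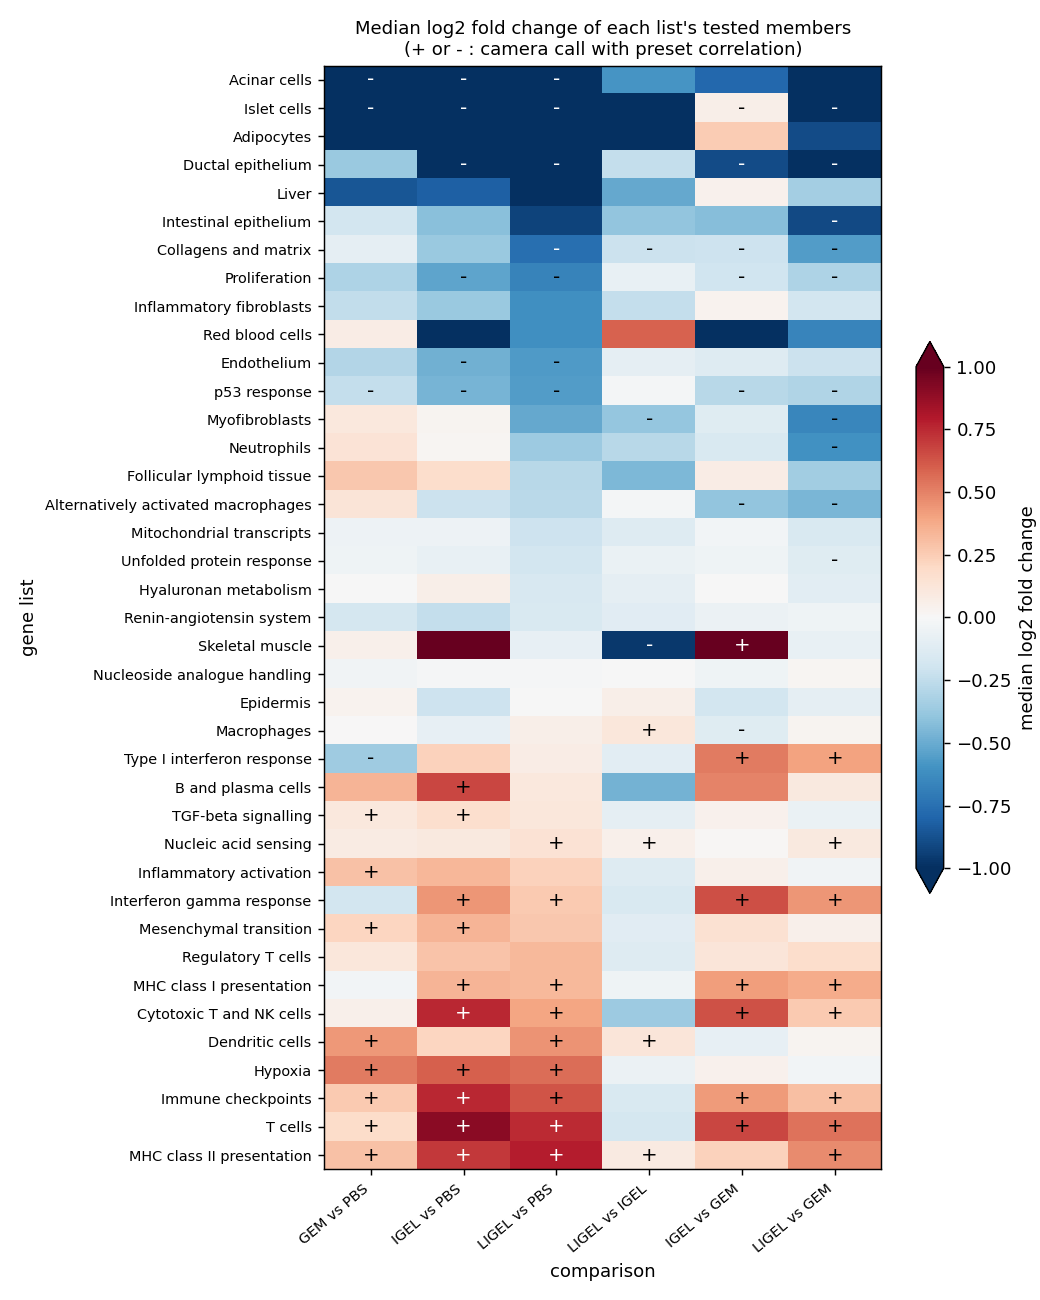
Median log2 fold change of each gene list (vertical) in each of the 6 comparisons (horizontal), colour from -1 to 1, with a plus or minus sign where camera called the list. The called lists number 12, 16 and 16 against PBS in GEM, IGEL and LIGEL, and 7, 14 and 18 in LIGEL against IGEL, IGEL against GEM and LIGEL against GEM.

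The first comparison asks what GEM did relative to control. Hypoxia genes, which serve low-oxygen metabolism, rose in GEM, with 17 of 18 members higher and a median log2 fold change of 0.52 (camera adjusted p = 4.62e-06, adjusted p = 0.704 with an estimated correlation). The glycolysis regulator Pfkfb4 stood at 39.4 ± 8.57 CPM against 28.1 ± 9.51, and the collagen-modifying enzyme P4ha1 at 251 ± 76.4 against 164 ± 68.2 (n = 6 each). Dendritic cell genes rose as well, 13 of 15 higher at a median of 0.43 (adjusted p = 0.000393, and adjusted p = 0.704 with an estimated correlation), with the cross-presenting cell marker Xcr1 at 1.94 ± 0.412 CPM against 0.826 ± 0.703. Type I interferon genes fell, with 20 of 24 members lower and a median of -0.36 (adjusted p = 0.000393, adjusted p = 0.704 with an estimated correlation). The antiviral synthetase Oas2 stood at 63.5 ± 40.05 CPM against 188 ± 257, and Usp18 at 26.95 ± 11.1 against 37.0 ± 13.2.

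Other lists were called in GEM against PBS too. Rising lists were immune checkpoints (9 of 13 higher, median 0.26, adjusted p = 0.0268), mesenchymal transition (8 of 11, 0.21, 0.0278), inflammatory activation (12 of 15, 0.30, 0.0310), MHC class II presentation (11 of 11, 0.29, 0.0310), TGF-beta signalling (14 of 18, 0.11, 0.0313) and T cells (17 of 18, 0.18, 0.0364). With an estimated correlation the adjusted p was 0.708 for T cells and 0.704 for the other 5. Genes of the p53 response, the damage-induced programme, fell with 16 of 22 lower at a median of -0.24 (adjusted p = 0.0313, adjusted p = 0.704 with an estimated correlation). The nuclease Aen was at 37.0 ± 7.72 CPM against 50.2 ± 7.19. Acinar genes (26 of 26 lower, median -1.73, adjusted p = 0.000218) and islet genes (16 of 16 lower, -1.70, 0.01002) fell too. Both had an adjusted p = 0.704 with an estimated correlation. Adjusted over the list alone, 0 members of the 12 lists passed in edgeR.

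Several GEM results depended on few libraries. Without PBS replicate 5 the acinar median was 1.23 (adjusted p = 0.899) and the islet median -0.39 (0.665), while proliferation genes fell by 0.55 with 27 of 27 lower (camera adjusted p = 7.64e-39, adjusted p = 0.135 with an estimated correlation), 21 of them passing adjusted over the list alone. With all samples the proliferation median was -0.31 (adjusted p = 0.0883). PBS replicate 5 had the lowest score of that list (4.08) and was singled out after its values were seen. Leaving out the A1 to A3 libraries ended the hypoxia call (-0.03, adjusted p = 0.847), the type I interferon call (-0.04, 0.9499), the acinar call (-0.89, 0.498) and the p53 call (-0.14, 0.218). With a term for them type I interferon genes rose, at a median of 0.23 (adjusted p = 0.00273), and calls ended for hypoxia (-0.00302, 0.976), acinar (-0.04, 0.551), islet (-0.19, 0.629), inflammatory activation (0.11, 0.166) and mesenchymal transition genes (0.11, 0.0604). The hypoxia median was 0.35 without GEM replicate 1, the type I interferon median -0.65 without GEM replicate 4, the acinar median -3.86 without GEM replicate 6, and the dendritic cell median 0.28 without PBS replicate 5.

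Leaving out 1 library also ended weaker GEM calls. The T cell median no longer passed without PBS replicate 2 (0.18), 3 (0.06), 4 (0.17) or 6 (0.15) or GEM replicate 2 (0.14), 4 (0.21) or 6 (-0.00), and was 0.65 without PBS replicate 1 and 0.29 without GEM replicate 1. The p53 median no longer passed without PBS replicate 1 (0.05), 3 (-0.24) or 6 (-0.30) or GEM replicate 2 (-0.22), 5 (-0.22) or 6 (-0.26), and was -0.44 without GEM replicate 4. The class II median no longer passed without PBS replicate 3 (0.14), 4 (0.25) or 6 (0.31) or GEM replicate 4 (0.18) or 6 (0.17), and was 0.59 without PBS replicate 5. The TGF-beta median no longer passed without PBS replicate 3 (0.14), 5 (-0.02) or 6 (0.13) or GEM replicate 4 (0.11) or 5 (0.09), and was 0.23 without PBS replicate 1 and 0.17 without PBS replicate 2. Inflammatory activation lost its call without PBS replicate 3 (0.35), 4 (0.24) or 5 (0.10) or GEM replicate 4 (0.26), and its median was 0.52 without PBS replicate 6. Checkpoints lost theirs without PBS replicate 3 (0.25) or 6 (0.30) or GEM replicate 4 (0.22), with 0.17 without PBS replicate 5, and mesenchymal transition without PBS replicate 5 (0.02) or 6 (0.22) or GEM replicate 5 (0.14).

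IGEL against PBS asks what that treatment did relative to control, and lymphocyte genes led the answer. T cell genes rose with 18 of 18 members higher and a median of 0.90 (camera adjusted p = 3.55e-07, adjusted p = 0.740 with an estimated correlation). The mean log2 CPM of the list was 2.58 to 3.31 in IGEL replicates 2 to 5. It was 1.01 and 1.14 in IGEL replicates 1 and 6, inside the PBS range of 0.71 to 2.77. Cytotoxic T and NK cell genes rose with 16 of 16 higher at 0.75 (4.19e-06, and adjusted p = 0.589 with an estimated correlation), 1 of them passing adjusted over the list alone. The killer protease Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260) stood at 21.9 ± 4.46 CPM against 8.13 ± 4.72, a log2 fold change of 1.43 ± 0.40 (SE, n = 6 each, adjusted p = 0.306). Immune checkpoint genes, which restrain T cells, rose with 11 of 13 higher at 0.76 (adjusted p = 3.45e-06, adjusted p = 0.105 with an estimated correlation), and 6 passed adjusted over the list alone. Ctla4 (ENSMUSG00000026011, chromosome 1, 60887000 to 60915832) stood at 2.71 ± 1.37 CPM against 0.613 ± 0.264 (log2 fold change 2.13 ± 0.50, adjusted p = 0.306). Cd274, which encodes the checkpoint ligand PD-L1 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), stood at 34.7 ± 7.23 against 20.96 ± 4.73 (0.73 ± 0.17, adjusted p = 0.306).

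Antigen presentation and interferon gamma genes rose in IGEL against PBS, while type I interferon genes were not called (19 of 24 higher, 0.23, adjusted p = 0.508). MHC class I presentation rose with 13 of 14 higher at 0.34 (adjusted p = 3.25e-05, adjusted p = 0.740 with an estimated correlation), with the light chain gene B2m at 1667 ± 172 CPM against 1188 ± 309 and the class I activator Nlrc5 at 224 ± 47.2 against 160 ± 43.3. Interferon gamma genes rose with 21 of 21 higher at 0.45 (adjusted p = 0.00254, adjusted p = 0.740 with an estimated correlation), with the T cell attractant Cxcl9 at 35.9 ± 32.9 CPM against 10.2 ± 3.78. Class II presentation rose with 11 of 11 higher at 0.71 (adjusted p = 0.0438), and B and plasma cell genes with 11 of 18 higher at 0.67 (adjusted p = 0.0171), 3 passing adjusted over the list alone. With an estimated correlation the adjusted p was 0.743 and 0.740. The antibody constant gene Ighg1 stood at 7.48 ± 11.3 CPM against 0.210 ± 0.284. Hypoxia genes rose with 17 of 18 higher at 0.60 (0.000315), mesenchymal transition with 9 of 11 at 0.34 (0.00666) and TGF-beta signalling with 13 of 18 at 0.17 (0.0181). For these 3 the adjusted p was 0.740 with an estimated correlation.

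Damage response, proliferation and ductal lists were lower in IGEL than in PBS. The p53 response fell with 19 of 22 lower at -0.47 (adjusted p = 2.99e-06, adjusted p = 0.589 with an estimated correlation), and 11 passed adjusted over the list alone. Aen stood at 33.6 ± 3.36 CPM against 50.2 ± 7.19 (log2 fold change -0.58 ± 0.14, adjusted p = 0.306), and the growth brake Btg2 at 27.05 ± 2.51 against 64.7 ± 44.8. Proliferation genes fell with 25 of 27 lower at -0.53 (adjusted p = 0.00282, adjusted p = 0.773 with an estimated correlation). Ductal epithelium fell with 13 of 16 lower at -1.34 (0.0151), islet genes with 16 of 16 at -1.67 (1.11e-05), acinar genes with 26 of 26 at -2.54 (3.25e-05) and endothelium with 13 of 15 at -0.48 (0.0388). For these 4 the adjusted p was 0.740 with an estimated correlation.

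Without PBS replicate 5 the fall of proliferation genes in IGEL was steeper, 27 of 27 lower at -0.77 (camera adjusted p = 6.43e-39, adjusted p = 0.0682 with an estimated correlation), and 24 passed adjusted over the list alone. That fit called 18 genes, all lower, and 3 belonged to this list. All 18 shared 1 edgeR adjusted p = 0.04995, just under the threshold. The library left out had the lowest score of this list (4.08) and was singled out after its values were seen. The mitotic kinesin Kif20a (ENSMUSG00000003779, chromosome 18, 34624624 to 34633265) stood at 59.4 ± 10.7 CPM in IGEL against 126 ± 43.2 in the other 5 PBS libraries (log2 fold change -1.09 ± 0.21, adjusted p = 0.04995). Kif18b was at 39.9 ± 7.92 against 82.2 ± 16.5, and the spindle gene Spag5 at 53.5 ± 10.2 against 109 ± 23.3, both with the same adjusted p. The acinar median there was 0.62 (adjusted p = 0.192), and with the A1 to A3 libraries also removed edgeR called 0 genes.

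T cell, cytotoxic, checkpoint, class I, p53, hypoxia and islet calls in IGEL against PBS held in all 12 fits that left out 1 library. The p53 median was then -0.30 without PBS replicate 1, the hypoxia median 0.20 without IGEL replicate 1, and the islet median -0.49 without PBS replicate 5 and -3.41 without IGEL replicate 4. Hypoxia no longer passed with the acinar covariate (0.12, adjusted p = 0.145), nor without PBS replicate 5 when that covariate was added (0.16, 0.113), the A1 to A3 libraries were removed too (0.20, 0.163) or PBS replicate 1 was removed too (0.29). Islet genes no longer passed in the latter 2 fits (-0.22, 0.0623, and 0.20, 0.192). Proliferation no longer passed without PBS replicate 2 (-0.38), 3 (-0.49) or 4 (-0.45), and interferon gamma genes without IGEL replicate 2 (0.20) or 4 (0.34). Class II lost its call without PBS replicate 3 (0.53), 4 (0.58) or 6 (0.73) or IGEL replicate 2 (0.32), 4 (0.70) or 5 (0.49), and B and plasma cells without PBS replicate 3 (0.53) or 4 (0.55) or IGEL replicate 2 (0.43), 4 (0.60) or 5 (0.27), with 1.10 without PBS replicate 5. Ductal epithelium lost its call without PBS replicate 1 (-0.63) or IGEL replicate 2 (-1.30), with -0.56 without PBS replicate 5. Endothelium lost it without PBS replicate 1 (-0.36) or 5 (-0.23) or IGEL replicate 1 (-0.41) or 2 (-0.55), without the A1 to A3 libraries (-0.40, adjusted p = 0.120) and with a term for them (-0.41, 0.0699). TGF-beta signalling lost it without PBS replicate 3 (0.20), 5 (0.05) or 6 (0.18) or IGEL replicate 5 (0.13), with 0.27 without PBS replicate 1, and mesenchymal transition without PBS replicate 5 (0.19).

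LIGEL against PBS asks what the last treatment did relative to control. Proliferation genes were lower, with 24 of 27 members down at a median of -0.67 (camera adjusted p = 0.00142, adjusted p = 0.754 with an estimated correlation). Without PBS replicate 5, 27 of 27 were lower at -0.90 (camera adjusted p = 8.97e-39, adjusted p = 0.139 with an estimated correlation), 23 passed adjusted over the list alone, and 17 were among the 173 genes called over all genes, of which 27 were higher and 146 lower. That library had the lowest score of this list (4.08) and was removed after the score was seen, so these values are no independent support. The PBS mean log2 CPM of the list was 6.68 with it and 7.20 without it, against 6.42 in LIGEL. The proliferation marker Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361) fell by 0.90 ± 0.21 on the log2 scale (adjusted p = 0.0357), to 265 ± 51.3 CPM from 495 ± 119 in the other 5 PBS libraries. The centromere gene Cenpa fell by 0.97 to 67.5 ± 8.22 CPM from 132 (adjusted p = 0.00837), Kif20a by 1.23 to 53.7 ± 9.21 from 126 (0.00929), and the mitotic gene Cenpf by 1.24 to 83.2 ± 18.9 from 197 (0.0102). Mean log2 CPM of the list ranged from 6.05 to 6.69 in LIGEL and from 6.69 to 7.60 in the other 5 PBS libraries.

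**Figure D3:**
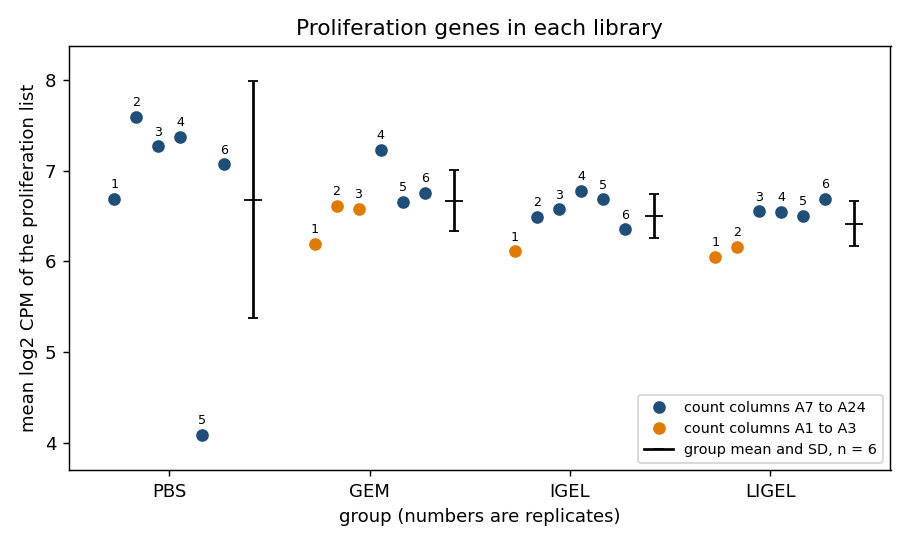
Mean log2 CPM of 27 proliferation genes per library by group, orange for the A1 to A3 libraries, bars for group mean and SD (n = 6). PBS replicate 5 lies at 4.08, the other 5 PBS libraries at 6.69 to 7.60, and LIGEL at 6.05 to 6.69.

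Of the other genes called in LIGEL without PBS replicate 5, the microtubule genes Psrc1 fell by 1.94 (adjusted p = 0.0223) and Ckap2 by 1.36 (0.0147). The vasoconstrictor Edn1 fell by 2.37 (0.0492), the chemokine Ccl3 by 1.90 (0.0477) and the fibroblast surface gene Lrrc15 by 1.87 (0.0495), from 9.30 ± 8.82 to 2.54 ± 0.869 CPM. The low-count genes Fbxl13, Cox6b2 and Vnn1 fell by 2.75, 2.86 and 4.08. Akr1cl stood at 0.00443 ± 0.0108 CPM against 1.38 ± 2.55 and Ano3 at 0 CPM in all 6 LIGEL libraries against 1.06 ± 1.80, so no fold is given for these. The calcium-binding gene Cabp4 rose by 1.87 (0.0373), from 0.432 ± 0.132 to 1.59 ± 0.473 CPM. With a term for the A1 to A3 libraries Psrc1, Ckap2 and Fbxl13 were still called, while Edn1 (adjusted p = 0.0770), Ccl3 (0.105), Lrrc15 (0.121), Cox6b2 (0.0716), Vnn1 (0.0812), Akr1cl (0.0771), Ano3 (0.102) and Cabp4 (0.0648) were not. Of the 173 genes, 57 changed at least 2-fold, 122 were also called with a term for the A1 to A3 libraries, and all 172 that could be fitted with all libraries had the same sign there, Ano3 having no fit. With the A1 to A3 libraries removed as well, edgeR called 0 genes.

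T cell genes rose in LIGEL with 18 of 18 higher at 0.74 (adjusted p = 7.32e-06), cytotoxic genes with 16 of 16 at 0.39 (0.00258), checkpoints with 11 of 13 at 0.63 (0.000365, 4 passing adjusted over the list alone), class II presentation with 11 of 11 at 0.79 (0.000365), dendritic cells with 12 of 15 at 0.45 (0.00686) and nucleic acid sensing with 16 of 18 at 0.15 (0.00628). For these 6 the adjusted p was 0.568 with an estimated correlation. Ctla4 stood at 2.46 ± 2.28 CPM against 0.613 ± 0.264, and the checkpoint gene Vsir at 96.4 ± 15.9 against 65.2 ± 12.7. Class I presentation rose with 13 of 14 higher at 0.33 (adjusted p = 0.000483, adjusted p = 0.588 with an estimated correlation), with H2-D1 at 2357 ± 383 CPM against 1778 ± 492. Hypoxia rose with 16 of 18 at 0.56 (0.000636, adjusted p = 0.669 with an estimated correlation) and interferon gamma genes with 19 of 21 at 0.26 (0.0201, adjusted p = 0.754 with an estimated correlation).

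Matrix and ductal lists were lower in LIGEL than in PBS, though the duct and tumour keratin Krt19 was not. Collagens and matrix fell with 22 of 27 lower at -0.75 (adjusted p = 0.0265, adjusted p = 0.754 with an estimated correlation). This fall rested largely on PBS replicate 1, which had the highest score of that list, a mean log2 CPM of 9.51. Without that library the median was -0.21 (camera adjusted p = 0.779). The proteoglycans Dcn and Lum stood at 36.7 ± 16.8 and 16.2 ± 8.58 CPM against 127 ± 131 and 52.5 ± 57.8, and Col1a1, the main fibrillar collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), at 4319 ± 1454 against 6860 ± 5638 (log2 fold change -0.67 ± 0.44, adjusted p = 0.386). Agtr1a, the angiotensin receptor that losartan blocks (ENSMUSG00000049115, chromosome 13, 30336441 to 30382867), stood at 0.429 ± 0.198 CPM against 2.79 ± 3.35 (-2.67 ± 0.75, adjusted p = 0.124). The SD of Agtr1a in PBS exceeded its mean there, so a few PBS libraries may carry the difference. Renin-angiotensin genes as a list were highest in PBS replicate 5, at a mean log2 CPM of 3.45. The PBS mean of that list was 2.29 with this library and 2.06 without it, against 1.91 in LIGEL. With no drug assigned to a group, the Agtr1a difference is not read as a drug effect. The p53 response fell with 19 of 22 lower at -0.56 (1.36e-05, adjusted p = 0.568 with an estimated correlation), and 11 passed adjusted over the list alone. Ductal epithelium fell with 11 of 16 lower at -1.57 (0.0168, adjusted p = 0.568 with an estimated correlation), 8 passing adjusted over the list alone, with the keratin Krt7 at 3.61 ± 3.74 CPM against 20.2 ± 24.2. Islet genes fell with 16 of 16 lower at -2.94 (1.36e-05, adjusted p = 0.568 with an estimated correlation). Endothelium fell with 12 of 15 lower at -0.56 (0.0168, adjusted p = 0.669 with an estimated correlation) and acinar genes with 26 of 26 at -3.11 (0.000614, adjusted p = 0.754 with an estimated correlation).

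Leaving out 1 library ended some LIGEL calls against PBS. Proliferation with the other 23 libraries no longer passed without PBS replicate 2 (-0.50), 3 (-0.66) or 4 (-0.60), nor without the A1 to A3 libraries (-0.52, adjusted p = 0.0749). Collagens no longer passed without PBS replicate 1 (-0.21), 2 (-0.71) or 4 (-0.77) or LIGEL replicate 1 (-0.64) or 6 (-0.64). Interferon gamma genes lost their call without PBS replicate 3 (0.22) or 6 (0.23) or LIGEL replicate 3 (0.21) or 5 (0.17), ductal epithelium without PBS replicate 1 (-0.97) or 6 (-1.65), with -0.62 without PBS replicate 5, and endothelium without PBS replicate 1 (-0.49) or 5 (-0.22) or LIGEL replicate 1 (-0.47). The acinar median was -0.12 without PBS replicate 5 (adjusted p = 0.219) and -4.87 without LIGEL replicate 4. Without PBS replicate 1 the T cell median was 1.18, the cytotoxic 0.77, the nucleic acid sensing 0.22 and the p53 median -0.34, and without PBS replicate 5 the class I median was 0.21 and the islet median -1.63, all still called. Without the A1 to A3 libraries hypoxia (0.18, adjusted p = 0.0860), endothelium (-0.43, 0.240) and acinar genes (-2.59, 0.0787) no longer passed, and with a term for them collagens (-0.48, 0.230), hypoxia (0.18, 0.174) and endothelium (-0.45, 0.0749) did not. Over 29 alternatives, the other list tests included, the nucleic acid sensing call ended in 6 and the hypoxia call in 9. At the gene level edgeR called 2 genes without PBS replicate 4.

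LIGEL against IGEL compares the latter groups directly, and each of the 7 called lists had an adjusted p = 0.891 with an estimated correlation. Matrix genes were lower in LIGEL, with 26 of 27 collagen and matrix members down at -0.21 (camera adjusted p = 0.00484) and 13 of 15 myofibroblast genes down at -0.39 (0.00300). The contractile genes Myl9 and Des stood at 9.57 ± 6.32 and 11.01 ± 2.56 CPM against 17.96 ± 13.3 and 15.6 ± 9.04, and Fmod at 8.02 ± 5.48 against 16.7 ± 12.8. Macrophage genes rose slightly, 12 of 14 higher at 0.11 (0.00300), with the growth factor receptor Csf1r at 192 ± 42.5 CPM against 150 ± 78.8. Class II presentation (9 of 11, 0.09, 0.00300), dendritic cells (9 of 15, 0.12, 0.0470) and nucleic acid sensing (13 of 18, 0.05, 0.0496) rose as well. Skeletal muscle genes fell with 14 of 14 lower at -0.96 (0.00189), 5 passing adjusted over the list alone.

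The muscle result in LIGEL against IGEL rested on IGEL replicate 4, the library with muscle transcripts, as the median was -0.01 without it (adjusted p = 0.614). Collagens no longer passed without IGEL replicate 5 (-0.12) or LIGEL replicate 1 (-0.20) or 6 (-0.18), with -0.41 without IGEL replicate 1 and -0.38 without LIGEL replicate 4, and myofibroblasts without IGEL replicate 5 (-0.27). Macrophages lost their call without IGEL replicate 1 (-0.01) or 6 (0.04), with 0.29 and 0.31 without IGEL replicates 2 and 5. Class II lost it without IGEL replicate 1 (-0.13) or 6 (-0.13), and its median lay between -0.13 and 0.50 over all 12 such fits. Dendritic cells lost it without IGEL replicate 1 (0.02), 3 (-0.02) or 6 (0.04) or LIGEL replicate 1 (0.08), 2 (-0.00) or 4 (0.10), with 0.24 without IGEL replicate 2. Nucleic acid sensing lost it without IGEL replicate 1 (0.04), 3 (0.04), 4 (0.04) or 6 (0.06) or LIGEL replicate 2 (0.07), 5 (0.04) or 6 (0.07), with 0.08 and 0.09 without IGEL replicates 2 and 5. Without the A1 to A3 libraries macrophages (0.03, adjusted p = 0.292), class II (-0.19, 0.896), dendritic cells (-0.04, 0.968) and nucleic acid sensing (0.06, 0.133) did not pass, while collagens (-0.35, 3.22e-05) and myofibroblasts (-0.40, 0.000192) did. With a term for them collagens (-0.13, adjusted p = 0.153) and dendritic cells (0.06, 0.0661) did not pass.

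IGEL against GEM compares those treatments, and interferon and class I genes led. GEM holds 3 of the A1 to A3 libraries and IGEL 1, and these libraries were lower in the same lists. With a term for them type I interferon genes no longer passed, while both interferon lists and class I passed without them, as given below. MHC class I presentation rose with 14 of 14 higher at 0.42 (camera adjusted p = 1.77e-16, adjusted p = 0.0858 with an estimated correlation), and 4 passed adjusted over the list alone. B2m stood at 1667 ± 172 CPM against 1202 ± 280, and H2-K1 at 2653 ± 358 against 1919 ± 431. Interferon gamma genes rose with 21 of 21 higher at 0.64 (1.25e-13, adjusted p = 0.298 with an estimated correlation) and type I interferon genes with 24 of 24 at 0.52 (3.16e-10, adjusted p = 0.467 with an estimated correlation). T cell genes rose with 18 of 18 at 0.67 (1.25e-09, adjusted p = 0.467 with an estimated correlation). Cytotoxic genes rose with 14 of 16 at 0.64 (1.87e-08, adjusted p = 0.133 with an estimated correlation), with Gzmb at 21.9 ± 4.46 CPM against 7.56 ± 4.49 (log2 fold change 1.53 ± 0.40, adjusted p = 1.0). Checkpoints rose with 10 of 13 at 0.42 (3.17e-06, adjusted p = 0.0761 with an estimated correlation), with Ctla4 at 2.71 ± 1.37 CPM against 0.947 ± 0.279.

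Macrophage, ductal and p53 lists were lower in IGEL than in GEM. Alternatively activated macrophage genes fell with 10 of 14 lower at -0.40 (0.00271, adjusted p = 0.467 with an estimated correlation), with the matrix protein gene Spp1 at 557 ± 129 CPM against 761 ± 118, and macrophage genes with 12 of 14 at -0.12 (0.0280, adjusted p = 0.820 with an estimated correlation). Ductal epithelium fell with 14 of 16 lower at -0.90 (4.04e-07, adjusted p = 0.0761 with an estimated correlation), with the tight junction gene Cldn4 at 10.9 ± 9.01 CPM against 36.9 ± 22.3. The p53 response fell with 20 of 22 lower at -0.28 (4.04e-07, adjusted p = 0.298 with an estimated correlation), collagens with 22 of 27 at -0.21 (0.00271, adjusted p = 0.820 with an estimated correlation) and proliferation with 26 of 27 at -0.20 (0.00907, adjusted p = 0.882 with an estimated correlation). Islet genes differed in sign by measure, with a median of 0.06, a mean of -0.06 and a camera call downward (5.53e-05, adjusted p = 0.664 with an estimated correlation). Skeletal muscle genes rose with 12 of 14 higher at 1.0 (0.00434, adjusted p = 0.595 with an estimated correlation), 5 passing adjusted over the list alone, but the median was -0.20 without IGEL replicate 4 (adjusted p = 0.358).

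IGEL replicate 2 carried part of the immune signal over GEM. Without it the medians were 0.24 for class I, 0.36 for interferon gamma, 0.20 for type I interferon, 0.42 for T cells and 0.40 for cytotoxic genes, all still called. Without GEM replicate 4 the type I interferon median was 0.81 and the p53 median -0.08, and without GEM replicate 6 the ductal median was -0.47. Collagens no longer passed without GEM replicate 4 (-0.05) or IGEL replicate 1 (-0.06), with -0.32 without GEM replicate 1 and -0.38 and -0.13 without IGEL replicates 5 and 6. Proliferation no longer passed without GEM replicate 4 (-0.05) or IGEL replicate 1 (-0.14), with -0.31 without GEM replicate 1, alternatively activated macrophages without GEM replicate 4 (-0.21) or IGEL replicate 4 (-0.31), and islet genes without IGEL replicate 1 (0.29). The islet median lay between -1.81 and 0.29 over the 12 such fits. Macrophages lost their call without GEM replicate 4 (0.05) or IGEL replicate 1 (0.01), 4 (-0.16) or 6 (-0.04), with a range of -0.28 to 0.05. GEM holds 3 of the A1 to A3 libraries and IGEL 1. Without them class I (0.25, adjusted p = 5.99e-06), interferon gamma (0.49, 3.20e-10) and type I interferon genes (0.39, 3.21e-07) still passed, while alternatively activated macrophages (-0.24, 0.476) and macrophages (-0.03, 0.629) did not. With a term for them type I interferon genes (0.06, 0.697), alternatively activated macrophages (-0.34, 0.101) and skeletal muscle genes (0.90, 0.101) did not pass.

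LIGEL against GEM gave 18 called lists. Class I presentation rose with 14 of 14 higher at 0.37 (camera adjusted p = 1.15e-11, adjusted p = 0.242 with an estimated correlation), with H2-K1 at 2585 ± 396 CPM against 1919 ± 431. Matrix genes fell, with 26 of 27 collagen and matrix members lower at -0.56 (2.22e-07, adjusted p = 0.485 with an estimated correlation) and 13 of 15 myofibroblast genes at -0.65 (3.57e-05, adjusted p = 0.335 with an estimated correlation). The collagen cross-linking enzyme Lox stood at 81.0 ± 32.4 CPM against 161 ± 65.7 (log2 fold change -0.99 ± 0.46, adjusted p = 0.999), Col12a1 at 176 ± 59.3 against 326 ± 96.5, and Myl9 at 9.57 ± 6.32 against 21.5 ± 9.22. Interferon gamma (20 of 21 higher, 0.44, 2.48e-08), T cell (18 of 18, 0.54, 2.57e-07) and cytotoxic genes (14 of 16, 0.26, 0.00253) rose, and islet genes fell (15 of 16 lower, -1.18, 1.95e-06), each with an adjusted p = 0.485 with an estimated correlation. Type I interferon genes (23 of 24, 0.40, 1.95e-06) and class II presentation (10 of 11, 0.47, 0.00164) rose, each with an adjusted p = 0.540 with an estimated correlation. The T cell gene Cd4 stood at 13.9 ± 6.41 CPM against 7.33 ± 3.78.

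**Figure D4:**
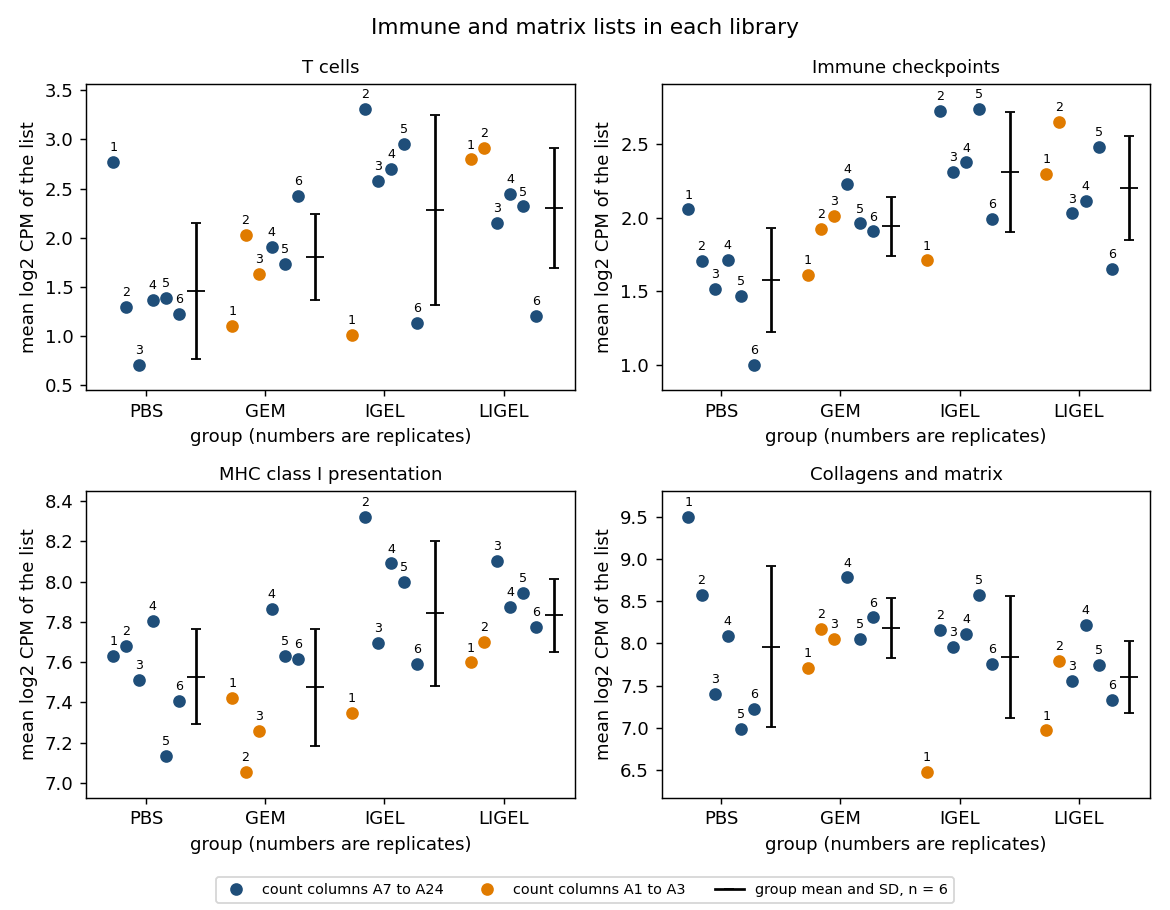
Mean log2 CPM per library of T cell, immune checkpoint, MHC class I and collagen and matrix genes by group, orange for the A1 to A3 libraries, bars for group mean and SD (n = 6). The T cell mean is 1.46 in PBS, 1.81 in GEM, 2.28 in IGEL and 2.31 in LIGEL, and the collagen mean is 7.60 in LIGEL against 8.18 in GEM.

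Ductal, intestinal and stress lists were lower in LIGEL than in GEM. Ductal epithelium fell with 13 of 16 lower at -1.20 (1.95e-06) and intestinal epithelium with 5 of 6 at -0.90 (0.00285), both with an adjusted p = 0.128 with an estimated correlation. Krt7 stood at 3.61 ± 3.74 CPM against 14.1 ± 7.29, and the stem cell marker Lgr5 at 0.305 ± 0.383 against 1.82 ± 1.26. The p53 response fell with 19 of 22 lower at -0.30 (4.19e-06, adjusted p = 0.369 with an estimated correlation), proliferation with 25 of 27 at -0.31 (0.00212, adjusted p = 0.837 with an estimated correlation), the unfolded protein response with 17 of 18 at -0.12 (0.0299, adjusted p = 0.502 with an estimated correlation), alternatively activated macrophages with 12 of 14 at -0.46 (0.0397, adjusted p = 0.553 with an estimated correlation) and neutrophils with 12 of 14 at -0.61 (0.0462, adjusted p = 0.722 with an estimated correlation). The neutrophil alarmin S100a9 stood at 1.78 ± 0.911 CPM against 5.40 ± 3.98. Checkpoints rose with 11 of 13 at 0.30 (0.00212, adjusted p = 0.335 with an estimated correlation) and nucleic acid sensing with 14 of 18 at 0.09 (0.0186, adjusted p = 0.485 with an estimated correlation).

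Several medians in LIGEL against GEM moved without GEM replicate 4. Collagens then lay at -0.36, type I interferon genes at 0.65 and p53 genes at -0.17, all still called, and proliferation no longer passed (-0.16, adjusted p = 0.179). The ductal median was -0.58 without GEM replicate 6, the interferon gamma median 0.28 without LIGEL replicate 5 and the checkpoint median 0.19 without LIGEL replicate 2, and nucleic acid sensing no longer passed without GEM replicate 6 (0.05). The unfolded protein response lost its call without GEM replicate 1 (-0.08), 3 (-0.08) or 6 (-0.11) or LIGEL replicate 3 (-0.09), 4 (-0.11) or 5 (-0.11), and alternatively activated macrophages without GEM replicate 1 (-0.43), 2 (-0.34), 3 (-0.41) or 4 (-0.22) or LIGEL replicate 3 (-0.38), 5 (-0.46) or 6 (-0.40). Neutrophils lost it without GEM replicate 2 (-0.24) or 4 (-0.34) or LIGEL replicate 3 (-0.48), 5 (-0.58) or 6 (-0.57), with -0.39 without GEM replicate 5. Without the A1 to A3 libraries, 3 of them in GEM and 2 in LIGEL, T cells (0.07, adjusted p = 0.598), cytotoxic genes (0.10, 0.689), checkpoints (0.21, 0.219), class II (0.16, 0.222), the unfolded protein response (-0.13, 0.0587) and alternatively activated macrophages (-0.32, 0.405) did not pass. Class I (0.23, 0.000138), type I interferon (0.42, 2.18e-10), collagens (-0.69, 2.28e-09) and myofibroblasts (-0.63, 0.000239) still did. With a term for them alternatively activated macrophages (-0.38, adjusted p = 0.128), neutrophils (-0.61, 0.111) and the unfolded protein response (-0.09, 0.167) did not pass, and with PBS replicate 5 removed as well type I interferon genes did not (0.12, 0.0526).

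Adjusted p-values of the lists spread widely over their alternatives. They ran from 4.64e-62 to 0.842 for proliferation in LIGEL against PBS and from 6.61e-62 to 0.951 in IGEL against PBS. For class I presentation they ran from 5.79e-25 to 0.794 in IGEL against GEM and from 2.65e-17 to 0.449 in LIGEL against GEM, and for T cells from 4.23e-18 to 0.754 in IGEL against PBS and from 2.54e-13 to 0.568 in LIGEL against PBS. Checkpoints in IGEL against PBS ran from 1.31e-10 to 0.274, and collagens in LIGEL against GEM from 2.28e-09 to 0.648. In GEM against PBS hypoxia ran from 8.28e-09 to 1.0 and type I interferon genes from 8.30e-08 to 1.0. With an estimated correlation 0 lists passed in all 6 comparisons. The exact permutation test of list means also passed 0. A single list at its smallest possible p of 0.00216 adjusts to 0.0844 over 39 lists, so 1 list alone could not pass it. Only IGEL against PBS and LIGEL against GEM held a list at that p. Fry passed 1 list, immune checkpoints in IGEL against PBS (adjusted p = 0.01004), and 0 in the other 5 comparisons. Without PBS replicate 5 it passed immune checkpoints and proliferation in IGEL (both adjusted p = 0.0159) and these and nucleic acid sensing in LIGEL against PBS (0.0427, 0.0127 and 0.0427). The H2, immunoglobulin, Prss and interferon-induced families hold closely similar genes, and reads shared among them were not separated here.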

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

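The tests on islet genes, on the A1 to A3 libraries, on keratins, on the acinar covariate and on Y-linked reads were chosen only after the results were seen. The scaling test was marked as chosen before, but it concerns PBS replicate 5, a library singled out after its values were seen. It was therefore not fixed before the data were examined. Of 212 groups of values tested, 22 held a library far from the other 5, where chance gives about 1 in 20 groups, or 10.6. PBS replicate 5 accounts for 8 of them, IGEL replicate 4 and PBS replicate 1 for 3 each, IGEL replicate 1 and LIGEL replicate 4 for 2 each, and GEM replicates 4 and 6, LIGEL replicate 6 and PBS replicate 6 for 1 each.

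PBS replicate 5 was low in mean log2 CPM of proliferation genes (4.08, others 6.69 to 7.60), mesenchymal transition (3.81, others 5.20 to 5.67), neutrophils (-0.90, others 1.29 to 2.60), hyaluronan metabolism (2.62, others 3.65 to 4.11), nucleic acid sensing (4.75, others 5.25 to 5.52) and nucleoside analogue handling (4.50, others 5.04 to 5.22). Its total of 27.1 M was below the other 5 (34.0 to 35.8 M). The digestive enzyme Cpa1 (ENSMUSG00000054446, chromosome 6, 30639218 to 30645363) reached 36023 CPM there (others 177 to 4671). Cpa1 was also far higher in 1 library of each other group, at 13188 CPM in GEM replicate 6 (others 1.26 to 2816), 7229 in IGEL replicate 4 (others 1.69 to 2363) and 4795 in LIGEL replicate 4 (others 5.09 to 865).

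Against scaling by a few very abundant genes as the whole explanation of PBS replicate 5 stands a test with the acinar genes taken out before scaling. Its proliferation score then still lay 2.56 log2 units below the lowest other PBS library, with an SD of 0.35 among those. Normal pancreas mixed into the piece may explain the library, as its islet genes stood at 4.99 against at most 2.96 in the other PBS libraries. Both values come from the library that raised the question, and no biological explanation was tested. How the piece was taken is not given in the sources used here.

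PBS replicate 1 was high in T cell genes (2.77, others 0.71 to 1.39), in Cd8a (36.3 CPM, others 5.96 to 11.1) and in p53 genes (6.02, others 4.76 to 5.13). LIGEL replicate 6 was low in cytotoxic genes (0.74, others 1.47 to 1.89), and LIGEL replicate 4 high in renin-angiotensin genes (2.66, others 1.56 to 1.90). IGEL replicate 1 was low in myofibroblast genes (2.997, others 3.92 to 4.45) and high in the unfolded protein response (7.18, others 6.66 to 6.84). PBS replicate 6 was high in red blood cell genes (3.37, others -2.56 to -0.48), and GEM replicate 4 in Acta1 (0.327 CPM, others 0 to 0.117). Explanations for these were not tested.

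IGEL replicate 4 was high in skeletal muscle genes (3.45, others 0.21 to 0.54) and in Acta1 (33.1 CPM, others 0 to 0.249), and it held 17 counts on the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y, where the other 23 libraries held 0. Reads from a male sample may be present, as these 17 counts need a male source. Muscle of the same animal as the only source cannot be told apart from muscle RNA of another sample. The bound first written, that such reads would argue against it, was wrong, because Y-linked reads show a male source in the library and not which RNA brought the muscle transcripts, and Xist at 639 CPM shows female RNA there too. No biological explanation was tested.

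The fall of proliferation genes in LIGEL against the other 5 PBS libraries had a median log2 fold change of -0.90. Against the A1 to A3 libraries as the whole explanation, the median without them was -0.73 (median SE of single genes 0.18). Against normal pancreas content as the whole explanation, it was -0.84 (median SE of single genes 0.16) with the acinar score as a covariate. No error of the list median itself was computed. Fewer tumour cells in the piece cannot be told apart from slower division. Krt8, Krt18 and Krt19 had a median of -0.000393 (median SE of single genes 0.24), and 3 keratins, which normal ducts also express, do not measure tumour content. The treatment itself stays open and was not tested apart from these.

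Other splits of the same libraries were counted, 40 of 462 per comparison with the real split included. For called lists, the real split exceeded all others tried in LIGEL against GEM alone, with 18 lists against at most 17, so 1 of 40 gave as many. That margin is 1 list in 1 of 6 comparisons, most splits were not tried, and the count was 16 without GEM replicate 2. Chance is therefore not excluded there. It could not be excluded in GEM against PBS (12 lists, highest other 15, 14 of 40), IGEL against PBS (16, 25, 13 of 40), LIGEL against PBS (16, 20, 8 of 40), LIGEL against IGEL (7, 22, 37 of 40) or IGEL against GEM (14, 22, 19 of 40). For genes the real count was 0 in all 6 comparisons, so 40 of 40 splits gave as many, and the highest other was 1 in GEM against PBS and 0 in the rest. With PBS replicate 5 removed and 60 splits, the real split of LIGEL against PBS exceeded all others tried (173 genes, highest other 0, 1 of 60). That library was removed after its low proliferation score of 4.08 was seen, which the splits do not account for. Chance is therefore not excluded there either. It could not be excluded for IGEL against PBS (18 genes, highest other 405, 3 of 60) or GEM against PBS (0 genes, highest other 1, 60 of 60). A split calling 405 genes points to a structure among the libraries apart from the groups.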

How the results depend on the processing

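All settings for the A1 to A3 libraries, every combination with PBS replicate 5 removed, and the exact permutation were chosen after seeing the data, and the other tests here were planned. Apart from fits leaving out 1 library, gene counts stayed within 1.5 times the reported count in 93 values and left it in 15, and list counts in 75 and 27. Where a number moved, the cause was not tested, unless stated.

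In place of 0 genes, DESeq2 called 42 in IGEL and 1224 in LIGEL against PBS, and voom with quality weights 66, 384 and 728 in GEM, IGEL and LIGEL against PBS. The acinar covariate gave 6 in LIGEL against PBS. Without PBS replicate 5, a term for the A1 to A3 libraries gave 105 in IGEL and 125 in LIGEL, the acinar covariate 91 and 349, and the replicate block 170 and 236, all against PBS. Without PBS replicates 1 and 5 the counts were 119, 692 and 521 in GEM, IGEL and LIGEL against PBS. With PBS replicate 5 and the A1 to A3 libraries removed edgeR called 0 genes in all 6 comparisons.

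With the correlation estimated, camera called 0 lists in all 6 comparisons, because the estimated correlations far exceeded the preset one (0.796 for T cells in GEM against PBS). Fry called 1 list in IGEL against PBS and 0 in the other 5. Without PBS replicate 5 fry called 2 lists in IGEL and 3 in LIGEL against PBS, and with the A1 to A3 term as well 2 and 5, where camera with the correlation estimated called 1, proliferation in IGEL (adjusted p = 0.0425). The exact permutation called 0 in all 6, with all libraries and with PBS replicate 5 removed. The smallest p it can give, 0.00216, adjusts to 0.0844 for a single list, so 1 list alone could not pass. With all libraries only IGEL against PBS and LIGEL against GEM reached that p. Elsewhere its smallest unadjusted p was 0.0195 in GEM against PBS and 0.00649 in LIGEL against PBS. It was 0.0411 in IGEL against GEM and 0.0649 in LIGEL against IGEL. There the smallest possible p does not account for the count of 0. LIGEL against IGEL gave 12 lists without the columns ending in _2, against 7 with all libraries. It gave 13 without the A1 to A3 libraries and 11 with PBS replicate 5 removed as well.

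Leaving out 1 library gave 0 to 18 genes in IGEL against PBS (18 without PBS replicate 5), 0 to 173 in LIGEL against PBS (173 without PBS replicate 5, 2 without PBS replicate 4) and 0 in each such fit of the other 4 comparisons. List counts ranged from 6 (without PBS replicate 3) to 20 (without PBS replicate 1) in GEM against PBS, 11 (without IGEL replicate 2) to 21 (without IGEL replicate 1) in IGEL against PBS, and 14 (without PBS replicate 1) to 17 (without LIGEL replicate 4) in LIGEL against PBS. They ranged from 5 (without IGEL replicate 6) to 12 (without IGEL replicate 1) in LIGEL against IGEL, 12 (without GEM replicate 4) to 17 (without GEM replicate 5) in IGEL against GEM, and 16 (without GEM replicate 2) to 19 (without GEM replicate 5) in LIGEL against GEM.

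Called lists had 2399 values under alternatives. In 1747 the direction was kept and the list still called, in 624 it was kept without a call, and in 28 it changed. Among those with the direction kept, the median changed sign in 43, 13 of them still called and 11 of these islet genes in IGEL against GEM. Direction here is camera's, so some of the 28 medians below kept their sign. With a term for the A1 to A3 libraries they were, in GEM against PBS, type I interferon 0.23 (called as a rise, adjusted p = 0.00273), acinar -0.0359, islet -0.19 and hypoxia -0.00302. With PBS replicate 5 also removed they were acinar 3.02 (adjusted p = 8.64e-08), type I interferon 0.30 (6.99e-05), islet 1.08 (0.00535), all 3 now called as rises, hypoxia -0.12, mesenchymal transition -0.0368 and inflammatory activation -0.0793 in GEM, and acinar 0.26 in LIGEL against PBS. With PBS replicate 5 and the A1 to A3 libraries removed they were acinar 2.15 (called as a rise, adjusted p = 0.000100), type I interferon 0.0562, hypoxia -0.0784 and mesenchymal transition -0.0331 in GEM, endothelium -0.10 in IGEL, and acinar 0.48 and endothelium 0.00936 in LIGEL against PBS. With the A1 to A3 libraries left out, dendritic cells in LIGEL against IGEL had -0.0364. With PBS replicate 5 removed and the acinar covariate, islet genes in GEM had -0.18 and endothelium in IGEL -0.0501 against PBS. Without PBS replicates 1 and 5 acinar genes had 2.01, islet genes 0.14 and mesenchymal transition -0.00840 in GEM, and endothelium 0.14 in IGEL and 0.0716 in LIGEL against PBS. Without IGEL replicate 4, the library with muscle transcripts, muscle genes had -0.00542 in LIGEL against IGEL and -0.20 in IGEL against GEM, where fits leaving out 1 library ranged from -1.34 to -0.00542 and from -0.20 to 1.20.

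The named genes made 487 pairs of a gene and a comparison. These pairs had 14113 values under alternatives, 346 of them with another sign, none past the threshold in that direction, and 188 now past the threshold in the same direction. Residuals of the 36 pairs of samples with the same replicate number had a mean correlation of -0.00610 (-0.593 to 0.708), against 0.000914 in 180 other pairs, and 6 of 24 samples matched best with their own number, so samples were not treated as paired. With the replicate number as a block and all libraries, edgeR called 0 genes in all 6 comparisons. The filter's minimum of 10 counts limits what could be tested among weakly expressed genes. Acta1 had no fit because it was high in IGEL replicate 4 alone.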

Other observations

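The tests on lists below were planned, while the look at Xist was chosen after the values were seen. Regulatory T cell genes, which mark suppressor lymphocytes, were not called in any of the 6 comparisons and had a median log2 fold change of 0.32 in LIGEL against PBS (6 of 9 higher, camera adjusted p = 0.232). Their master regulator Foxp3 stood at 1.42 ± 0.835 CPM in LIGEL against 0.833 ± 0.490 in PBS (adjusted p = 0.323). Inflammatory fibroblast genes lay at -0.61 (12 of 14 lower, adjusted p = 0.124) and renin-angiotensin genes at -0.15 (8 of 13 lower, adjusted p = 0.472), 1 higher and 2 lower passing adjusted over the list alone, and 0 without PBS replicate 5. Adipocyte genes lay at -2.03 (5 of 5 lower, adjusted p = 0.105), 4 passing adjusted over the list alone, but at -1.13 with 0 passing without PBS replicate 5 (adjusted p = 0.755), and PBS replicate 1 was the next highest. Hyaluronan metabolism had a median of -0.16 (adjusted p = 0.887) and nucleoside analogue handling, the genes that take up and activate drugs such as gemcitabine, -0.01 (adjusted p = 0.913), and camera's direction was upward for both.

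The remaining lists not called in any comparison hold tissues a piece of tumour can also contain. In LIGEL against PBS liver genes lay at -1.41 (5 of 5 lower, adjusted p = 0.0757; -0.45 without PBS replicate 5), follicular lymphoid tissue at -0.27 (4 of 5 lower, 0.773), epidermis at -0.00 (0.651), red blood cells at -0.61 (5 of 5 lower, with camera's direction upward, 0.277) and mitochondrial transcripts at -0.21 (10 of 13 lower, 0.310). The mean log2 CPM of red blood cell genes was instead higher in LIGEL, at 0.48 against -0.73 in PBS, where replicate 6 alone was high at 3.37 and the others lay from -2.56 to -0.48. Mitochondrial transcripts lay at -0.02 without PBS replicate 5 (6 of 13 higher). Krt19, a duct and tumour keratin, stood at 93.3 ± 18.8 CPM in LIGEL, 72.1 ± 35.3 in IGEL, 91.7 ± 19.7 in GEM and 73.4 ± 59.6 in PBS (n = 6 each).

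IGEL replicate 3 held 3 counts of Xist, the transcript of the inactive X chromosome in female cells, or 0.0856 CPM. The other 23 libraries held at least 111 CPM. Its Y-linked counts were 0, and its leukocyte gene Ptprc stood at 101 CPM. The sex of the animals is not given in the sources used here.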
